A study of Mus musculus with 2 samples.

How the data were processed

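Per the labels, lineage-depleted bone marrow cells of aged mice were stained with sort antibodies, a TotalSeq-C surface antibody panel and 1 hashtag antibody per condition, LSK cells were sorted, and the pools were mixed before loading on a 10x Genomics 5' kit. The 2 sequencing samples are the RNA and the antibody-tag library of this 1 loading. The authors deposited 1 matrix per condition, which holds raw UMI counts per feature and cell, not normalized, for 32285 genes, 126 surface tags (9 of them isotype controls) and 2 hashtags. Per the submitters' processing notes, Cell Ranger 7.0.0, Seurat 4.3.0 and the mm10 build were used, whereas the matrix header names version 7.0.1 of Cell Ranger. The annotation release, the filters on barcodes and the way cells were assigned to hashtags are not given in the sources used here. The condition of each matrix was taken from its name and checked against the hashtag that the labels pair with that condition. No barcode occurred in both matrices.

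Gene names came from the matrices, and 32158 of the 32285 gene identifiers were found in a separate name table. Coordinates came from the RefSeq annotation of GRCm38.p6, the assembly behind mm10. The control matrix held 4026 barcodes and the chelator matrix 4037, where the labels speak of about 20000 sorted cells per sample. Cells were kept with at least 500 genes and under 10% mitochondrial UMIs, which removed 57 and 39 barcodes. Scrublet, as implemented in scanpy, called 3 doublets in each matrix, 0.0744% of all barcodes. So low a share means that the caller did not work here, and doublets remain: from cells with both Xist and Y-linked transcripts (34 and 50), doublets were estimated at 1.76% of control and 3.25% of chelator cells. A cell was counted as having Xist from 2 UMIs with no Y-linked UMI, and as having Y-linked transcripts from 1 UMI over 4 Y-linked genes with no Xist. Cells with both had at least 2 UMIs of each kind. The other 563 control and 507 chelator cells were left without a sex.

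Expression was compared by summing UMI counts over the cells of a pool and dividing by total gene UMIs, giving CPM (counts scaled to library size) and their ratio, chelator over control, with an exact conditional binomial 95% interval. UMI sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals. Differences of shares carry intervals built from the 2 single-share intervals. With 1 pool per condition these cover counting error only, and no p-value was computed. A gene list was summarised by the median log2 ratio of its members with at least 50 UMIs, its interval from 2000 resamplings of the counts, and its percentile among 10000 random lists of the same size drawn within 100 ranks of mean expression. In all, 34 lists were used.

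For cell classes, 2000 variable genes without cell-cycle genes, 30 components and 15 neighbours were used with Leiden clustering at resolution 1 on both pools together, without integration. A cluster was named from fixed marker genes, when at least 3 markers and 25% of a type's markers were 1.5-fold higher than in the other cells and seen in 10% of its cells, with 10 CPM added in these folds. It stayed unnamed unless its 10 leading genes held at least 1 marker of that type and no more of any other. Clusters 2 and 3 among the HSC-like ones had the immediate-early gene Egr1 among their leading genes. Tag gates used a 2-component mixture of centred log ratios per tag. Cycle scores were the mean log expression of S or G2M genes minus that of 50 control genes per gene from 25 expression bins.

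Genes were named by a rule fixed before the data were examined: with at least 200 UMIs in whole LSK (100 within a class) and a UMI in 5% of cells of either pool, the 12 highest and 12 lowest ratios whose interval left out 1 (5 and 5 in the smaller classes). Mitochondrial, immunoglobulin, T-cell receptor and predicted genes were left out, 16 genes of iron biology and HSC identity were always given, and up to 4 members of a list described. For tags it was the 6 highest and 6 lowest plus the sort and gate markers. The filters, the clustering, the marker genes, the lists and 15 alternatives were also chosen before the data were examined.

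Other choices were made after values had been seen: the 9 lists given with example genes, the 5 lists whose medians answer a comparison, the 1.25-fold window, the size of 0.1 used for opposite sexes, the marker share of 25%, and 7 added alternatives. So 22 alternatives were tried. In the smaller classes the alternatives were run for the named genes and, of the lists, for those 5 alone. The added ones were cells with Xist alone, cells with Y-linked transcripts alone, both sexes weighted equally, cells with both sex markers left out, clustering without immediate-early and heat shock genes, HSC-like cells without cluster 11, and the sums without the 2 control cells richest in haemoglobin.

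The others were no cell filter, a stricter one (1500 genes, 5% mitochondrial UMIs), called doublets kept, edgeR TMM or median-of-ratios scaling, the mean of per-cell CPM, other UMI minimums (500 UMIs, or none with 0.5 CPM added, for lists, and the named-gene minimum doubled), Leiden resolutions 0.5 and 1.5, cell-cycle genes kept in the clustering, centred log ratios for tags, gates split at the median and no thinning. The scaling factors moved log2 ratios by at most 0.036 in any class.

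The intervals were tested on simulated pool sums, drawn as Poisson counts from the real means. Such draws hold counting error alone, without UMIs gathered in few cells. The shares below therefore check the computation and are not error rates of these data. In whole LSK, over 12512 genes, the interval left out 1 for 4.92% of unchanged genes, and on the right side for 92.5% of genes changed 1.25-fold and 100% of those changed 1.5-fold. In HSC-like cells, over 11425 genes, these shares were 4.59%, 77.6% and 97.0%. Of 34 lists simulated with no change of their own, 8.82% in whole LSK and 5.88% in HSC-like cells fell outside the central 95% of random lists. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors alone.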

Results

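Single-cell RNA and surface-protein profiles (CITE-seq) were taken from bone marrow LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction that holds haematopoietic stem cells (HSCs) and multipotent progenitors (MPPs). The mice had received the iron chelator deferoxamine at 50 mg/kg, or the vehicle HBSS, daily for 7 days in every 4 weeks. The courses began at about 6 months of age and ran for 13 months. The stated purpose was to learn how lasting iron chelation acts on HSCs as they age. There was 1 pool of cells per condition, told apart by a hashtag antibody, and both pools were loaded together as 1 RNA and 1 antibody-tag library. The number of mice behind each pool was not given in the sources used here. There was thus no replicate, no difference was tested across animals, and every interval below covers counting error only.

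The control pool held 4026 barcodes with 63370466 gene UMIs, and the chelator pool 4037 barcodes with 66573361. About 20000 cells had been sorted per sample, so the barcodes made up 20.1% and 20.2% of that number; the pools had been mixed in equal amounts, which sets the ratio of cell numbers. After filtering, 3966 control and 3995 chelator cells were kept, with medians of 13704.5 and 14453 gene UMIs and of 4244 and 4389 genes per cell. The median mitochondrial share was 2.08% in both. The pool's own hashtag was the stronger in 4025 of 4026 control and 4037 of 4037 chelator barcodes, and the other pool's hashtag gave 1.29% and 0.343% of hashtag UMIs.

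Both pools held cells of both sexes, in different proportions. Xist, the RNA of the inactive X chromosome, marked 1417 control and 897 chelator cells, while Y-linked transcripts alone marked 1952 and 2541. Cells with Xist thus made up 42.1% (95% Clopper-Pearson interval 40.4 to 43.7) of the sexed control cells and 26.1% (24.6 to 27.6) of the sexed chelator cells. Values within each sex are therefore set beside many of the pooled ones, and many reversals within a sex are also gathered with the effects of processing choices.

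The first comparison asked whether the chelator regimen went with a different make-up of the LSK compartment. HSC-like cells, led by Sult1a1, Clu, Nupr1, Procr and Vwf, made up 30.9% (95% interval 29.5 to 32.4) of control and 32.1% (30.6 to 33.6) of chelator cells. Lymphoid-primed-like cells, led by Dntt, Satb1 and Flt3, made up 12.3% and 11.5%. Megakaryocyte-primed-like cells, led by Pf4, Itga2b and Gp1bb, made up 5.75% and 6.78%. Granulocyte-monocyte-primed-like cells, led by Elane and Mpo, made up 1.64% and 1.53%, and erythroid-primed-like cells, led by Car1 and Klf1, 1.49% and 1.10%. A group of T, NK or innate lymphoid-like cells, led by Ccl5 and Cd7, held 20 control and 9 chelator cells.

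The interval of each pooled class difference included 0, although that of megakaryocyte-primed-like cells, 1.03 points (-0.0478 to 2.12), did not do so under several alternatives. It was 1.91 (0.755 to 3.08) with the stricter cell filter, 1.26 (0.154 to 2.37) at Leiden resolution 1.5 and 1.13 (0.0378 to 2.23) with cell-cycle genes kept in the clustering, and lay above 0 as well with cells of both sex markers or stress genes left out. Unnamed cluster 8, however, had 11 of 16 megakaryocyte-primed markers up and 14 of 17 cycling markers. It was not counted in the main class and differed the other way, at 3.91% (3.33 to 4.56) of control and 3.40% (2.86 to 4.01) of chelator cells. The HSC-like difference was 1.18 points (-0.881 to 3.23), and 0.564 points when immediate-early and heat shock genes were left out of the clustering. Egr1 was among the leading genes of the 2 larger HSC-like clusters, but its part in this was not tested. Clusters without a name held 47.4% and 46.8%, among them cycling cells led by histone genes or by Ube2c and Cenpa. This similar total hid opposite differences. Cluster 1, led by Mgst1 and Rgs1, held 20.4% (19.1 to 21.7) of control and 17.4% (16.2 to 18.6) of chelator cells. Cluster 5, cycling cells led by histone genes, held 9.30% (8.42 to 10.3) and 11.7% (10.8 to 12.8). Among cells with Xist, however, cluster 5 held 11.4% and 8.92%. HSC-like cells came from clusters 2, 3 and 11, with 544, 574 and 108 control and 716, 545 and 21 chelator cells. Cluster 2 held 13.7% (12.7 to 14.8) of control and 17.9% (16.7 to 19.1) of chelator cells. It was larger in the chelator pool in both sexes, at 14.3% and 19.8% with Xist and 12.3% and 16.8% with Y-linked transcripts. Cluster 3 held 14.5% and 13.6%, and cluster 11 2.72% and 0.526%. Ratios within HSC-like cells take in this make-up, whose part was tested for cluster 11 alone. Among cells with Xist the HSC-like share was 22.4% in control and 30.5% in chelator cells, a difference of 8.10 points (4.34 to 11.9), and the lymphoid-primed-like share was 12.6% and 8.36%. Among cells with Y-linked transcripts the HSC-like share was 32.9% and 30.9%, a difference of -2.05 points (-4.84 to 0.731), and the erythroid-primed-like share 1.64% and 0.669%.

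Surface tags gave a second view of the compartment. The HSC gate (CD135 and CD48 negative, CD150 positive) held 29.3% (27.9 to 30.8) of control and 32.8% (31.4 to 34.3) of chelator cells. The MPP4 gate (CD135 positive, CD150 negative), which holds lymphoid-biased progenitors, held 37.9% (36.4 to 39.5) and 32.2% (30.7 to 33.6). The MPP3 gate (CD48 positive alone), which holds myeloid-biased progenitors, held 12.7% and 15.4% (16.1% and 15.8% with Xist, 11.2% and 15.5% with Y-linked transcripts), the MPP1 gate 13.9% and 14.2%, and the MPP2 gate 2.32% and 2.48%. Of the cells in the HSC gate, 75.2% were HSC-like by RNA. The HSC gate share was 24.0% against 33.4% in cells with Xist, and 31.2% against 32.0% in cells with Y-linked transcripts. The MPP4 share was lower in the chelator pool in both sexes, at 40.6% against 28.3% and 38.7% against 35.0%. The gate classes are ranges of tag signal, and 22.2% of cells lay within 0.25 of the CD135 threshold, whose tag was itself lower in the chelator pool. A difference in staining between the pools would move the gate shares too and was not tested.

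**Figure D1:**
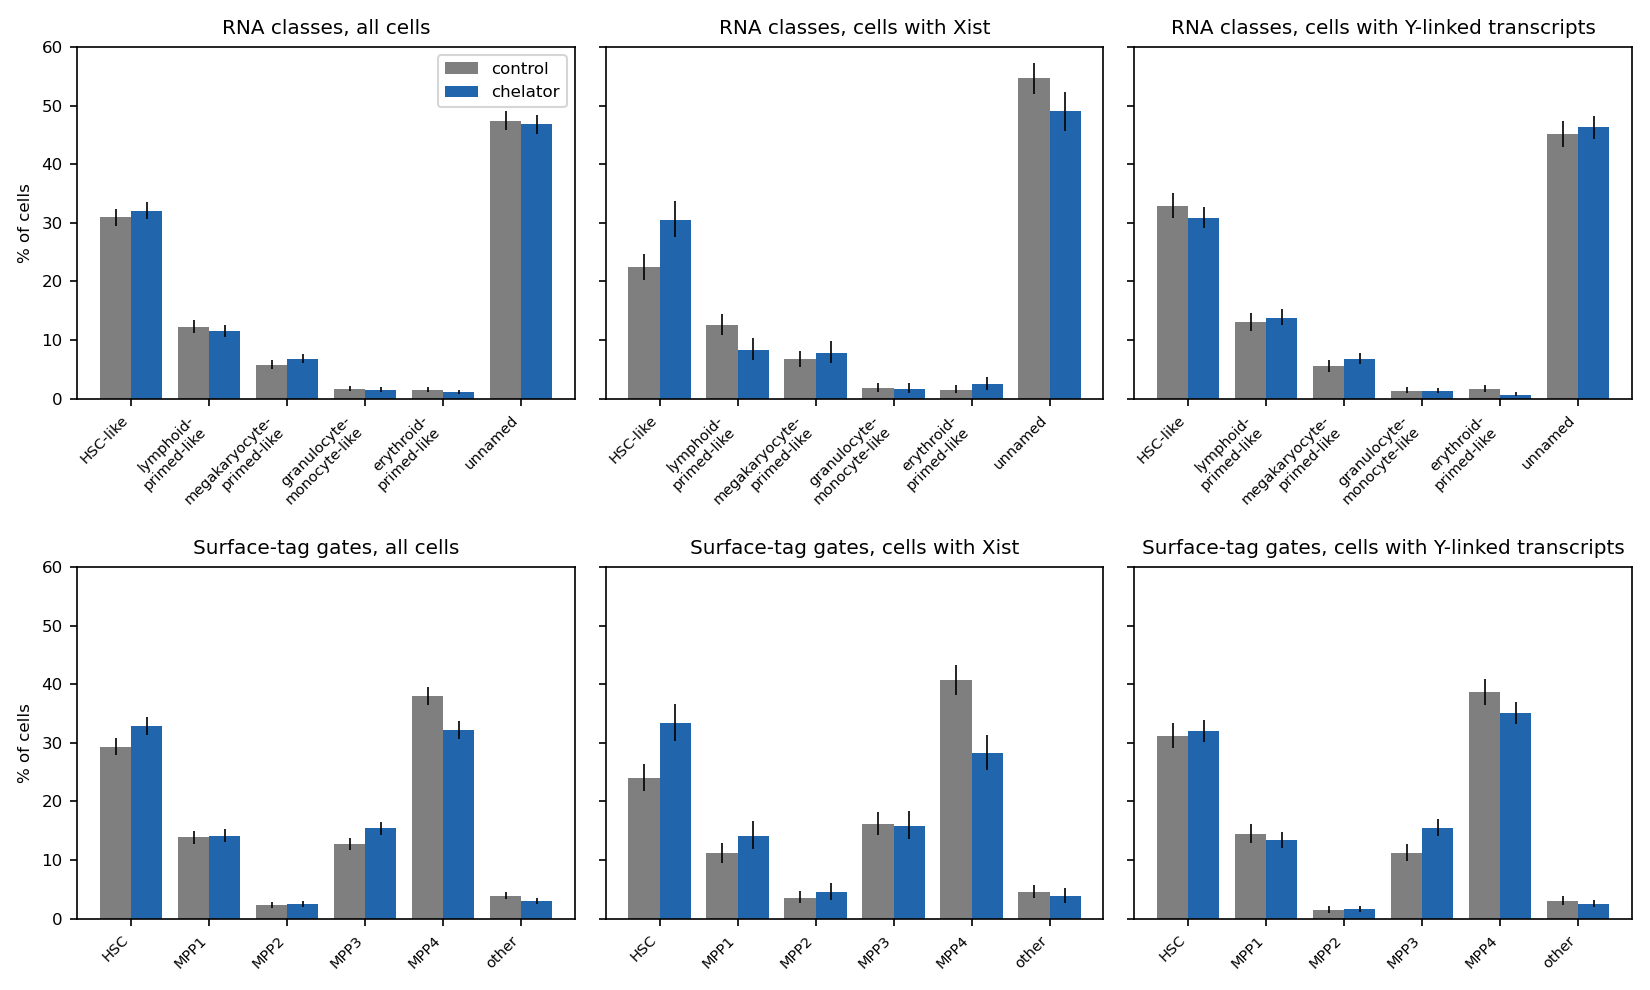
Percent of kept cells in each RNA class (upper panels) and each surface-tag gate (lower panels), in control (grey) and chelator (blue) pools, for all cells, cells with Xist and cells with Y-linked transcripts; bars start at 0 and whiskers are exact 95% binomial intervals. The HSC-like share was 30.9% and 32.1% over all cells, but 22.4% and 30.5% among cells with Xist.

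Cycle scores, from lists of S-phase and G2 and M-phase genes, were compared after each cell was thinned to 5000 UMIs, which left out 159 control and 138 chelator cells. Cells with an S or G2M score above 0 made up 42.4% (40.9 to 44.0) of control and 45.1% (43.5 to 46.7) of chelator LSK cells, and 42.2% and 45.3% without thinning. In HSC-like cells they made up 2.77% (1.91 to 3.86) and 2.96% (2.09 to 4.05) (2.77% and 3.35% without thinning). In lymphoid-primed-like cells the shares were 51.1% and 56.1%, and in megakaryocyte-primed-like cells 74.2% and 68.9%. These class shares depend on the clustering, which set many cycling cells apart in unnamed clusters. Clusters 5, 6, 8 and 9 had 15, 6, 14 and 9 of 17 cycling markers up, and HSC-like clusters 2, 3 and 11 had 0. The low HSC-like share was thus partly set in advance. The whole-LSK difference had opposite signs in the sexes, -4.18 points in cells with Xist and 5.64 points in cells with Y-linked transcripts. Free RNA can enter such scores, and they were not read as division.

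The next comparison set the RNA of all LSK cells of the pools side by side, and it was close for most genes. Of 9833 genes with at least 1000 UMIs, 99.1% lay inside the window of fold given with the methods. The genes that were higher in the chelator pool were led by Mid1 (ENSMUSG00000035299), a microtubule-associated ubiquitin ligase encoded on the X chromosome at its boundary with the pseudoautosomal region, which was 2.12-fold higher (95% interval 1.95 to 2.31). Its counts were 816 UMIs (95% Poisson interval 761 to 874) in control and 1820 UMIs (1737 to 1906) in chelator cells, or 12.9 and 27.4 CPM (counts scaled to library size). Also among the highest were genes that cells switch on within minutes of a stimulus, namely Nr4a1, an orphan nuclear receptor, 1.77-fold higher (95% interval 1.66 to 1.90), Fos, a subunit of the AP-1 transcription factor, 1.49-fold higher (95% interval 1.46 to 1.52), and Egr1, a zinc-finger transcription factor, 1.44-fold higher (95% interval 1.41 to 1.47). Lower in the chelator pool were the stress-induced chaperones of the Hsp70 family, Hspa1b (ENSMUSG00000090877), 4.82-fold lower (95% interval 4.32 to 5.38), and Hspa1a (ENSMUSG00000091971), 4.29-fold lower (95% interval 3.76 to 4.91).

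Hspa1b was at 28.6 CPM in control and 5.95 CPM in chelator cells, and Hspa1a at 18.1 and 4.21 CPM; both were lower in each sex of whole LSK. In HSC-like cells Hspa1b was at -1.10 from 96 and 49 UMIs (-0.42 with Xist and -1.22 with Y-linked transcripts), while Hspa1a had 1.71 and 1.36 CPM with Xist and 1.20 and 1.14 CPM with Y-linked transcripts, with overlapping intervals. This near-identical pair lies close together in the GRCm38.p6 annotation (chromosome 17, 34956429 to 34959238 and chromosome 17, 34969359 to 34972156), so reads shared between them make the split uncertain. A larger ratio was that of the adult beta-globin Hbb-bs, 191 CPM in control and 13.3 CPM in chelator cells (log2 ratio -3.84), with Hbb-bt at -1.22. This came from 2 control cells, which held 11579 of the 12042 control Hbb-bs UMIs. Without them the log2 ratio was 0.86 for Hbb-bs and 0.099 for Hbb-bt. That alternative was chosen after the values were seen, and it left out no chelator cell. The 2 richest chelator cells held 444 of 882 Hbb-bs and 322 of 2104 Hbb-bt UMIs. The signs without the control cells thus rest on a removal from 1 pool and do not show a higher level in the chelator pool.

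The other genes with the highest ratios were Mtus2 (log2 ratio 0.60), Mettl5os (0.57), Bok, a BCL2 family member (0.53), Dynlt1b, a dynein light chain (0.51), Dusp18 (0.49), Sytl5 (0.49) and Zfp951 (0.49). Those with the lowest ratios were Cdk5rap1, a tRNA-modifying enzyme (-0.86), Ncam2 (-0.83), Myl10 (-0.78), Gimap1os (-0.71), the cytokine Il4 (-0.69), Phyhd1 (-0.54) and Mab21l2 (-0.50). The sex-linked Kdm5d (0.50) and Xist (-0.69) followed the sex make-up of the pools. Several of these ratios had opposite signs in the sexes: Fos was -0.21 in cells with Xist and 0.94 in cells with Y-linked transcripts, Cdk5rap1 0.37 and -1.55, and Myl10 -0.52 and 0.32. Mid1 (0.47 and 1.48), Nr4a1 (0.37 and 0.99) and Egr1 (0.52 and 0.52) were higher in both.

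**Figure D2:**
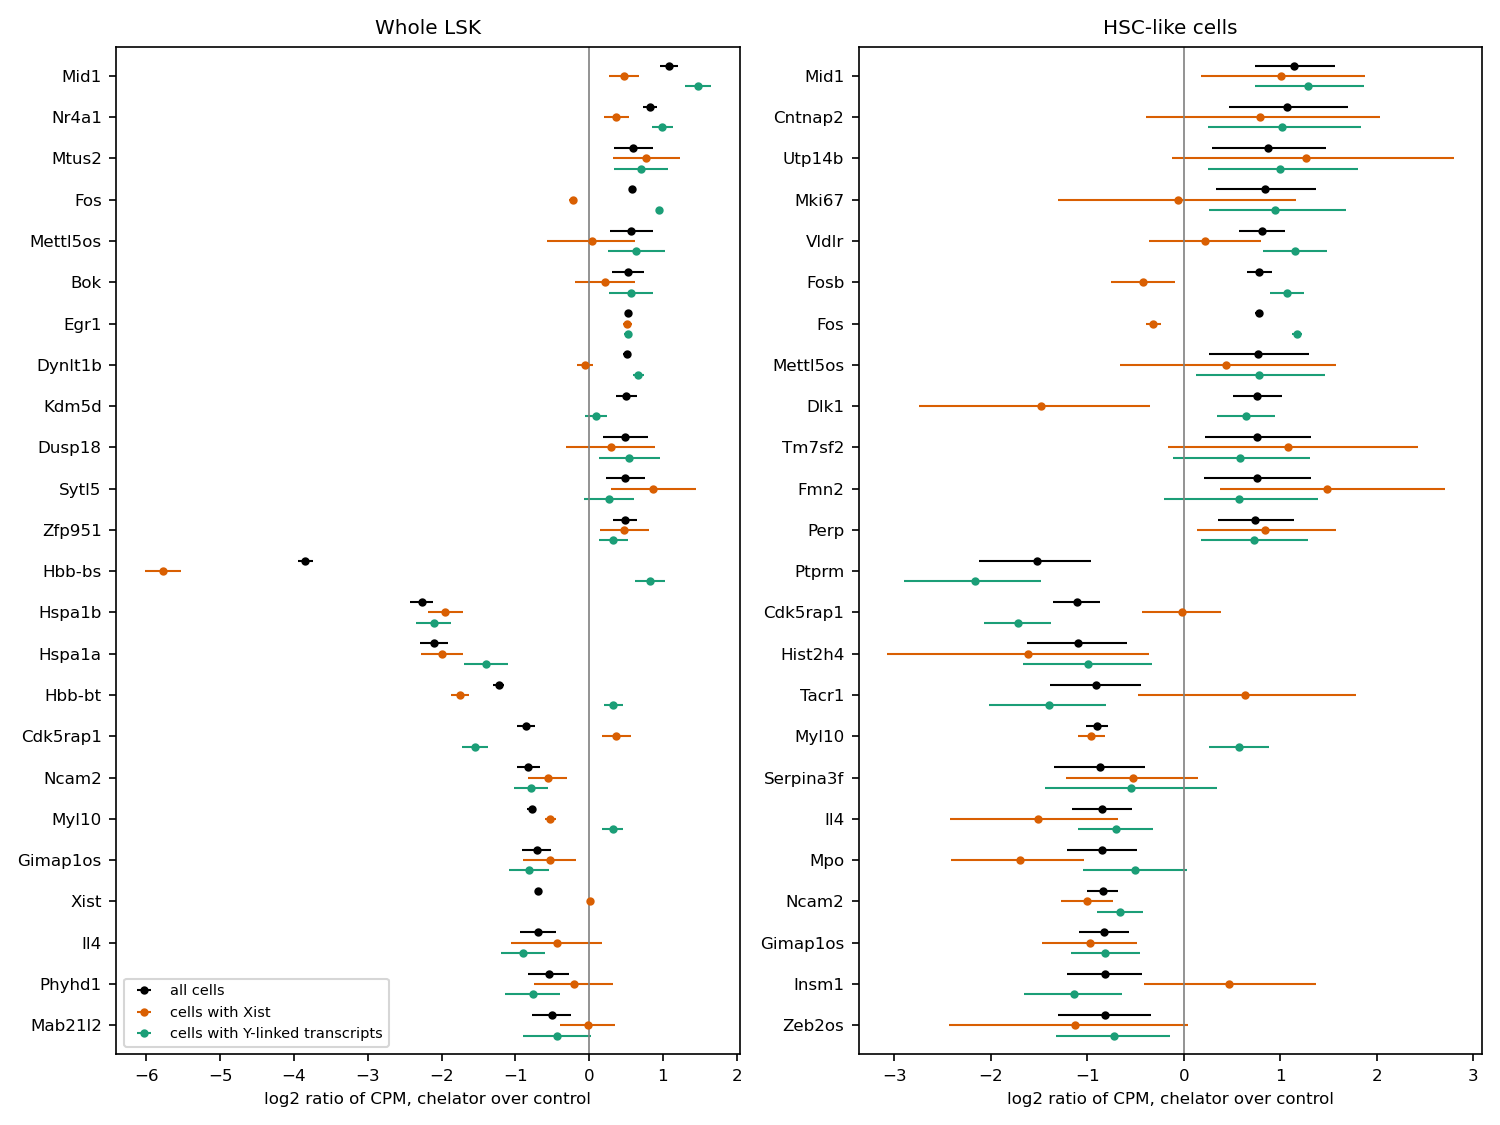
Log2 ratio of CPM, chelator over control, for the 12 genes with the highest and the 12 with the lowest ratios in whole LSK (left) and in HSC-like cells (right), with 95% counting intervals, for all cells (black), cells with Xist (orange) and cells with Y-linked transcripts (green). Mid1 lay at 1.08 and 1.15, and Fos at -0.21 and 0.94 in the sexes of whole LSK.

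Genes of iron biology differed little. Over 27 measured genes of iron uptake, storage and export the median log2 ratio was -0.00041 (-0.030 to 0.020), with 13 members above 0 and 14 below. Ferritin heavy chain Fth1 was at 0.024 and light chain Ftl1 at 0.0050, the transferrin receptor Tfrc at -0.080 (-0.22 to 0.064), the ferritin-degradation receptor Ncoa4 at -0.074 and the iron exporter ferroportin, Slc40a1, at 0.20 (-0.18 to 0.57) from 112 and 135 UMIs. The ferroxidase Heph was at 0.023 and haem oxygenase Hmox1 at 0.22. Heme synthesis genes had a median of -0.055, with Alad at -0.017, Urod at 0.035, the erythroid enzyme Alas2 at -0.67 and Abcb6 at -0.41. Medians were -0.0069 for iron-sulfur cluster assembly, 0.013 for hypoxia-inducible factor targets, -0.015 for antioxidant and ferroptosis genes and -0.032 for iron- and oxoglutarate-dependent chromatin enzymes. The Tip60 acetyltransferase complex had a median of 0.00061, with its catalytic subunit Kat5 at -0.022.

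Among the remaining lists in whole LSK, immediate-early and AP-1 genes stood farthest above 0, with a median of 0.26 (0.22 to 0.29). Of 20 members 16 lay above 0, among them Zfp36, a regulator of mRNA decay, at 0.25, while Jun was at -0.00046; the median lay at percentile 100 of 10000 random lists of matched expression, as a description of these libraries. Within the sexes it was -0.19 and 0.51. Genes known to be higher in aged stem cells had a median of 0.092, with 30 of 37 above 0, at percentile 100. Fos, Egr1, Jun and Zfp36 belong to both lists. The adhesion receptor Selp, an age marker of HSCs, was at 0.21 and Vwf at -0.013. The median of the ageing list was 0.34 in cells with Xist and -0.016 in cells with Y-linked transcripts.

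Stem cell identity genes had a median of -0.012, with Hlf at 0.0021, Mecom at 0.030, Procr at -0.20, Sult1a1 at 0.31, Ifitm1 at -0.099 and Ifitm3 at 0.042; within the sexes the median was 0.18 and -0.10. Myc itself, the growth-promoting transcription factor, was at 0.17 (0.14 to 0.19) and higher in both sexes, while Myc targets and ribosome biogenesis genes had a median of -0.000034, with Npm1 at 0.0056, Ncl at 0.0086 and Rrp9 at -0.13. Erythroid genes had a median of -0.48, with 22 of 22 below 0. The alpha-globins Hba-a1 (-3.89) and Hba-a2 (-4.62) lay farthest down and carbonic anhydrase Car2 at -0.044, and the erythroid median was -0.21 without the 2 haemoglobin-rich control cells. It was 0.043 in cells with Xist, -0.47 in cells with Y-linked transcripts and -0.32 with the sexes weighted equally. Heat shock and unfolded protein genes had a median of -0.073, with the abundant Hsp90ab1 at 0.023 and Hspa8 at -0.048; the median was -0.11 in cells with Xist, -0.0041 in cells with Y-linked transcripts and -0.038 with the sexes weighted equally. Interferon gamma and antigen presentation genes had a median of -0.054, with H2-K1 at -0.042, H2-D1 at -0.046 and Gbp6 at -0.31. That median was 0.0066 in cells with Xist, 0.0057 in cells with Y-linked transcripts and -0.0021 with the sexes weighted equally, where Gbp6 was at 0.12, so the list was not lower within either sex. The chemokine Cxcl9 was at -4.00, from 228 and 15 UMIs. It had a UMI in under 5% of cells of either pool, and the spread of its UMIs over cells was not examined. In HSC-like cells with Y-linked transcripts it was at 1.22 (-2.41 to 6.94). Among the receptors of LSK subsets, Cd34 was at -0.018, Flt3 at -0.067, Kit at 0.038 and Ly6a, which encodes Sca-1, at -0.14.

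Other list medians were smaller than 0.1 in size. They were 0.040 for S phase and 0.097 for G2 and M phase genes (with Xist -0.029 and -0.13, with Y-linked transcripts 0.092 and 0.12), -0.018 for quiescence, -0.0061 for p53 targets, -0.017 for the TGF-beta response, -0.041 for NF-kB and inflammatory genes, 0.027 for the type I interferon response (0.13 with Xist and -0.047 with Y-linked transcripts) and -0.078 for MHC class II (-0.12 and 0.031). For metabolism they were 0.068 for cholesterol synthesis, -0.00036 for fatty acid synthesis, 0.0060 for fatty acid oxidation, -0.039 for lipid droplet and lipolysis, -0.039 for autophagy and lysosome, and 0.027 for glycolysis. Nuclear-encoded oxidative phosphorylation genes were at 0.014 (-0.033 with Xist and 0.042 with Y-linked transcripts), mitochondrially encoded genes at 0.0058 (0.085 and -0.037) and ribosomal proteins at 0.0036. Lineage lists were at 0.0099 for megakaryocyte and platelet, 0.0068 for granulocyte and monocyte and -0.029 for lymphoid genes (-0.14 with Xist and -0.0040 with Y-linked transcripts). Cholesterol synthesis lay at percentile 99.99 of random lists in all cells, with a median of 0.15 in cells with Xist and -0.030 in cells with Y-linked transcripts.

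**Figure D3:**
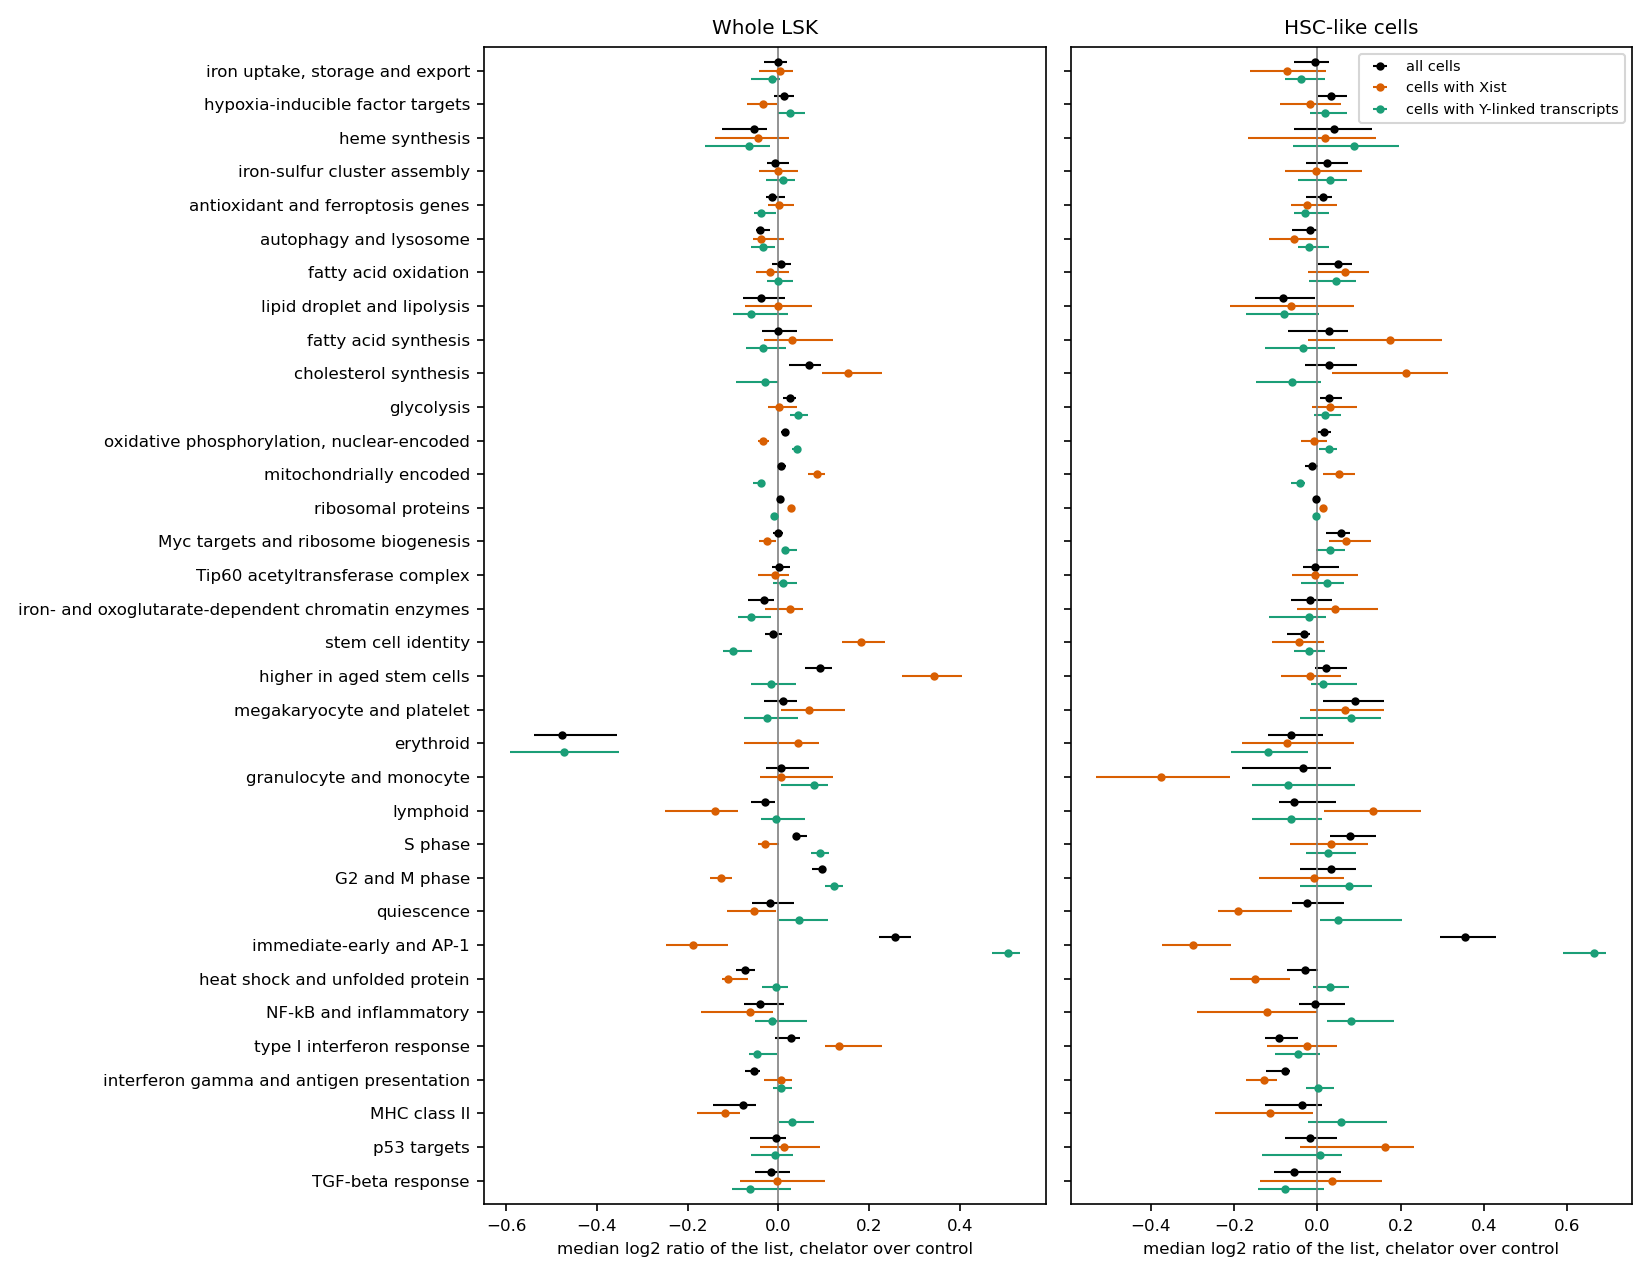
Median log2 ratio, chelator over control, of each of the 34 gene lists in whole LSK (left) and HSC-like cells (right); whiskers are 95% intervals from resampled counts, for all cells (black), cells with Xist (orange) and cells with Y-linked transcripts (green). Immediate-early and AP-1 genes lay at 0.26 and 0.36 over all cells, and at -0.30 and 0.66 in the sexes of HSC-like cells.

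The question behind the study concerns the stem cells, so the same comparison was made within HSC-like cells, 1226 control and 1282 chelator, with 14492997 and 15827188 gene UMIs. Immediate-early genes were among those higher in the chelator pool. Fos was 1.71-fold higher (95% interval 1.67 to 1.76), at 606 and 1039 CPM, and its relative Fosb 1.72-fold higher (95% interval 1.57 to 1.89). Mid1 was again among the highest, 2.21-fold higher (95% interval 1.67 to 2.96), and so were Vldlr, a lipoprotein receptor, 1.75-fold higher (95% interval 1.48 to 2.07), and the imprinted gene Dlk1, 1.70-fold higher (95% interval 1.43 to 2.02). Lower in the chelator pool were Cdk5rap1, 2.16-fold lower (95% interval 1.83 to 2.55), Il4, 1.80-fold lower (95% interval 1.45 to 2.23), and the myeloid granule enzyme Mpo, 1.80-fold lower (95% interval 1.40 to 2.31). In cells with Xist, however, Fos (-0.32), Fosb (-0.42) and Dlk1 (-1.48) were lower in the chelator pool, against log2 ratios of 1.17, 1.06 and 0.64 in cells with Y-linked transcripts.

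Further genes with high ratios were Cntnap2 (1.07), Utp14b (0.87), the proliferation marker Mki67 (0.84, from 49 and 96 UMIs), Mettl5os (0.77), Tm7sf2, a sterol reductase (0.76), Fmn2 (0.75) and the p53 target Perp (0.74). Further genes with low ratios were Hist2h4 (-1.10), Tacr1 (-0.91), Myl10 (-0.90), Serpina3f (-0.87), Gimap1os (-0.83) and Zeb2os (-0.82). Ptprm (-1.53), Insm1 (-0.82) and Ncam2 (-0.84) were also low, and these are leading genes of cluster 11, which came mostly from the control pool. Leaving out that cluster was an alternative chosen after the values were seen. Without it, Ptprm was at 1.74 (0.28 to 3.51) and Insm1 at 0.54 (-0.0015 to 1.10). Vwf, at -0.17 with all clusters, was then at 0.091 (-0.030 to 0.21). The intervals of Insm1 and Vwf included 0, so these were no longer lower but not shown to be higher. Of 4967 genes with at least 1000 UMIs in these cells, 99.3% lay inside the same window.

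In HSC-like cells the immediate-early and AP-1 list had a median of 0.36 (0.29 to 0.43), with 18 of 20 members above 0. It was -0.30 in cells with Xist and 0.66 in cells with Y-linked transcripts, and 0.37 when these genes were left out of the clustering. Iron uptake, storage and export genes had a median of -0.0063 (-0.056 to 0.029). Among them Fth1 was at -0.038, Ftl1 at -0.061, Tfrc at -0.28 (-0.71 to 0.15), Ncoa4 at -0.12, the iron importer Slc11a2 at 0.54 and Slc40a1 at 1.11 (0.26 to 2.02), the last from only 17 and 40 UMIs. The Tip60 complex had a median of -0.0066 and Kat5 was at -0.028, while Myc was at 0.23 (0.17 to 0.30), at 0.20 and 0.25 in the sexes. Myc targets and ribosome biogenesis genes had a median of 0.056, with 26 of 36 above 0, among them the importin Ipo4 at 0.19.

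Stem cell identity genes had a median of -0.033, with 21 of 30 below 0; Hoxb5, a marker of long-term HSCs, was at -0.33, Hlf at -0.13 (0.080 with Xist and -0.18 with Y-linked transcripts), Mecom at 0.0082, Procr at -0.19 and Sult1a1 at 0.26 (-0.13 and 0.45). The ageing list had a median of 0.021 (-0.0048 to 0.071), and 0.12 without cluster 11. Selp was at 0.19, Alcam at 0.32 and the metallothionein Mt1 at 0.29. Type I interferon response genes had a median of -0.093, with 25 of 32 below 0, but it was nearer 0 within each sex, at -0.025 and -0.047, where both intervals included 0, and -0.055 with the sexes weighted equally. For interferon gamma and antigen presentation it was -0.078, with 26 of 30 below 0; it was -0.13 in cells with Xist, 0.0021 in cells with Y-linked transcripts and -0.076 with the sexes weighted equally. Kit was at 0.040, Cd34 at 0.022, Flt3 at -0.057 and Ly6a at -0.15.

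Lymphoid-primed-like cells (487 control, 459 chelator) shared some leading genes with the whole compartment. Mid1 was 2.38-fold higher (95% interval 1.96 to 2.89) and Nr4a1 2.14-fold higher (95% interval 1.72 to 2.68), and higher ratios were also found for St3gal5, a ganglioside synthase (0.82), Hist1h2bn (0.78) and Rbbp9 (0.77). Hspa1b was 7.62-fold lower (95% interval 5.29 to 11.3) and Hspa1a 4.42-fold lower (95% interval 2.87 to 7.04). The mast cell protease Cpa3 was 2.67-fold lower (95% interval 2.17 to 3.29) and Cd7 2.06-fold lower (95% interval 1.38 to 3.11), and Xist was at -1.16. The medians were 0.38 for immediate-early and AP-1 genes (0.014 with Xist and 0.45 with Y-linked transcripts), 0.13 for the ageing list (-0.068 and 0.19), 0.042 for stem cell identity, -0.037 for Myc targets and 0.037 for iron genes. Myc was at 0.20, Flt3 at -0.072 and Tfrc at 0.079.

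Megakaryocyte-primed-like cells (228 control, 271 chelator) had more transcripts of genes of aged stem cells in the chelator pool. The ageing list had a median of 0.26 (0.18 to 0.36), with 29 of 36 members above 0, and it was above 0 in both sexes, at 0.46 and 0.22. The metallothionein Mt2, a metal-binding protein on that list, was 2.13-fold higher (95% interval 1.69 to 2.70), the small GTPase Rhoj 2.54-fold higher (95% interval 1.81 to 3.62), and Selp was at 0.29 and Vwf at 0.31. Dlk1 (1.91), Hbb-bt (1.47) and Hbb-bs (3.50) had the other high ratios, although 2 cells held 133 of the 191 chelator Hbb-bs UMIs. Lower were Hspa1b (-2.93), the matrix protein gene Emilin2 (-1.22), Cpa3 (-1.14), Cd48 (-1.09) and Cst7 (-1.07). Other medians were 0.34 for immediate-early and AP-1 genes (-0.33 with Xist and 0.82 with Y-linked transcripts), 0.094 for stem cell identity (0.21 and -0.030), -0.028 for Myc targets and 0.014 for iron genes.

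Surface protein was compared by the share of tag UMIs. The pools carried different hashtags and were mixed only before loading. A difference in staining between them thus cannot be told apart from a difference in surface protein, also where both sexes go the same way. CD71, the transferrin receptor protein, was lower in the chelator pool, at 4.66 and 3.82 tag UMIs per cell (log2 ratio of shares -0.45, -0.48 to -0.42). It was lower in each sex (-0.40 and -0.41). In HSC-like cells its ratio was -0.49, but its 2.76 and 2.18 UMIs per cell there lay within the range of isotype controls, which reached 2.84 and 3.35 (G0114F7), as did CD135 with 2.52 and 1.99. CD62P, or P-selectin, was at -0.56 in whole LSK and -0.39 in HSC-like cells, opposite in sign to its gene Selp. CD93 (-0.48 and -0.43), CD135, the FLT3 receptor (-0.42 and -0.49), and CD34 (-0.40 and -0.64) were lower too, with CD11c at -0.37 in whole LSK and CD45 at -0.37 in HSC-like cells. Higher were the platelet integrin chains CD41 (0.35 and 0.42) and CD61 (0.24 and 0.23), the lectin CD371 (0.22 and 0.22) and CD169 (0.21 and 0.28). In HSC-like cells with Xist and with Y-linked transcripts, however, CD169 was at -0.12 and 0.050, CD41 at 0.076 and 0.50, and CD61 at 0.062 and 0.29.

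Ly.49A (0.19) and CD185 (0.50) were also higher in whole LSK, and CD4 (0.22) and CD49b (0.21) in HSC-like cells. CD4, however, had only 0.784 and 1.02 UMIs per cell there. That is near the lowest isotype control, RTK4174, with 0.790 and 0.756. The tags behind the sort and the gates, CD135 apart, lay closer to 0 in whole LSK: CD117 at -0.11, Sca-1 at 0.011, CD150 at -0.011 and CD48 at 0.041. In HSC-like cells they were at -0.11, -0.024, -0.074 and -0.042. Of the 9 isotype controls, which bind no mouse antigen, MOPC.21 differed most (0.38), at 1.73 and 2.52 UMIs per cell, so tags with few UMIs per cell lie near background. Per-cell centred log ratios gave smaller differences for several tags: in whole LSK CD71 was at -0.34, CD135 at -0.22, CD11c at -0.070, CD41 at 0.20, CD61 at 0.15 and CD185 at -0.023, and in HSC-like cells CD34 at -0.34, CD135 at -0.15, CD169 at 0.13 and CD4 at 0.032. By summed shares in cells with Xist and in cells with Y-linked transcripts, CD185 was at -0.10 and 0.74, CD11c at -0.75 and 0.13, and CD48 at -0.53 and 0.35 in whole LSK. By centred log ratios, however, CD11c was at -0.19 and -0.030 in these cells, with the same sign in both sexes.

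**Figure D4:**
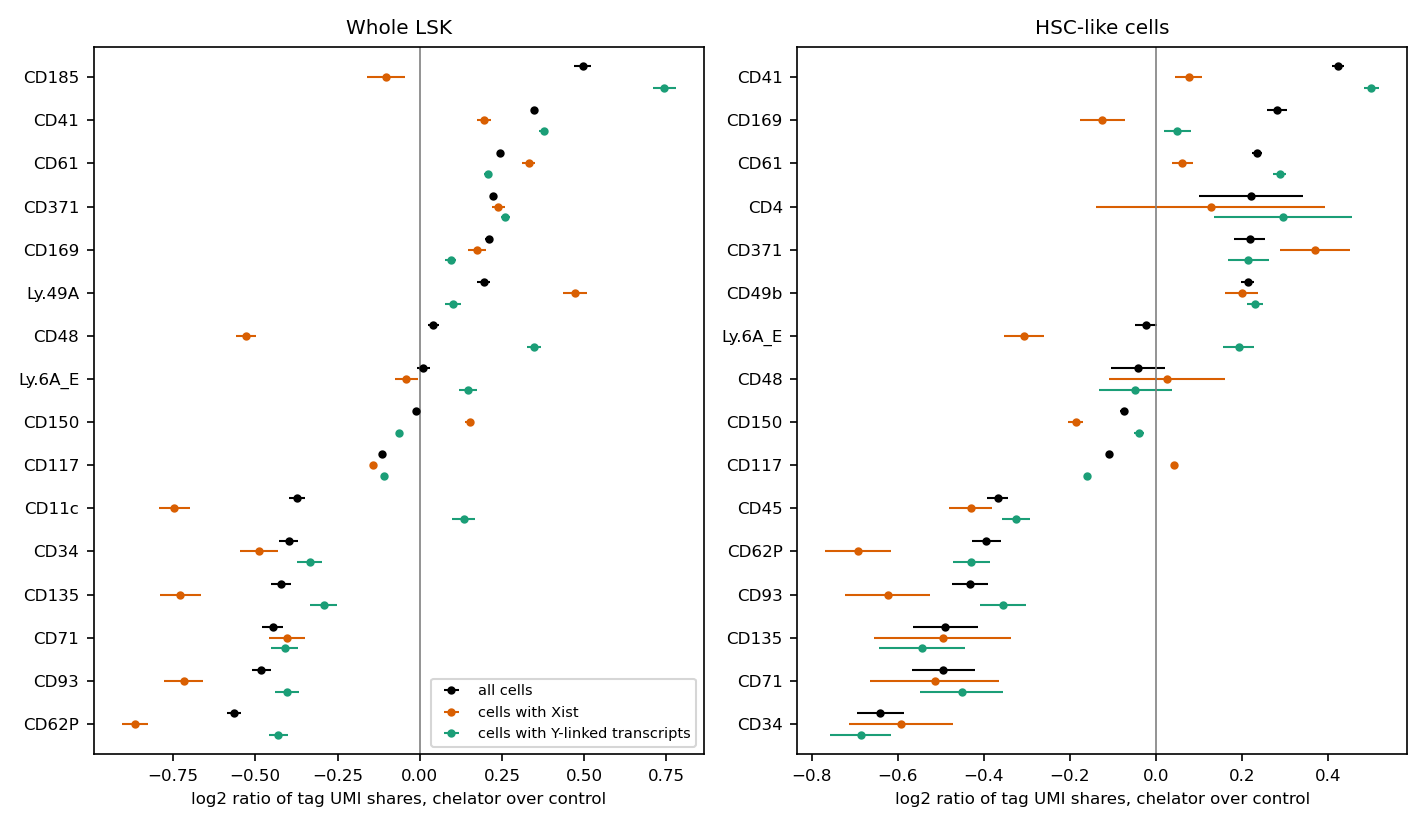
Log2 ratio of tag UMI shares, chelator over control, for the named surface tags in whole LSK (left) and HSC-like cells (right), with 95% counting intervals, for all cells (black), cells with Xist (orange) and cells with Y-linked transcripts (green). CD71 lay at -0.45 and -0.49, and CD41 at 0.35 and 0.42.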

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

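The comparison of the sexes and all tests in this part were chosen after the results were seen. Among the lists and named tags reported and the genes named by the fixed rules, in 27 results the cells with Xist and the cells with Y-linked transcripts lay on opposite sides of 0, with both 95% counting intervals leaving out 0 and both log2 ratios (or medians) at least 0.1 in size. The difference between the sexes was not tested, since each sex came from an unknown number of animals in 1 pool per condition. Values below are given for cells with Xist first and for cells with Y-linked transcripts second.

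In whole LSK these were the immediate-early and AP-1 list at -0.19 (-0.25 to -0.11) and 0.51 (0.47 to 0.53), G2 and M-phase genes at -0.13 and 0.12, and the genes Jun at -0.79 and 0.45, Zfp36 at -0.40 and 0.49, Car2 at 0.13 and -0.16, Fos at -0.21 and 0.94, Cdk5rap1 at 0.37 and -1.55, Myl10 at -0.52 and 0.32, Vwf at 0.59 and -0.25, Hlf at 0.22 and -0.16 and Mecom at 0.27 and -0.11. Hbb-bs was at -5.77 and 0.82 and Hbb-bt at -1.75 and 0.33, where the control value with Xist rests mostly on 2 cells. Whole-LSK ratios also take in the make-up of the cells, whose part was not tested. The HSC-like share differed by 8.10 and -2.05 points in the sexes, and the share of S or G2M cells by -4.18 and 5.64. Within HSC-like cells Hlf was at 0.080 (-0.019 to 0.18) with Xist. Neither Hlf nor Mecom met the rule there, while Vwf did. In HSC-like cells the immediate-early and AP-1 list was at -0.30 (-0.37 to -0.21) and 0.66 (0.59 to 0.69), Fos at -0.32 and 1.17, Fosb at -0.42 and 1.06, Dlk1 at -1.48 and 0.64, Myl10 at -0.96 and 0.57, Vwf at 0.23 and -0.29, Ly6a at -0.37 and 0.10, Ifitm1 at -0.43 and 0.12 and Sult1a1 at -0.13 and 0.45. In megakaryocyte-primed-like cells the immediate-early and AP-1 list was at -0.33 and 0.82. The tags CD185, CD11c and CD48 in whole LSK were at -0.10 and 0.74, -0.75 and 0.13 and -0.53 and 0.35, and Sca-1 in HSC-like cells at -0.31 and 0.19. These tag values are ratios of summed shares. By per-cell centred log ratios CD11c was lower in both sexes (-0.19 and -0.030), whereas Sca-1 in HSC-like cells stayed opposite (-0.23 and 0.18). CD185 was at -0.023 by them over all cells.

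The pattern weighed first is the higher level of immediate-early genes in the chelator pool. The sex make-up of the pools cannot account for it alone, since the list median in HSC-like cells with Y-linked transcripts was 0.66 within that sex. A handling difference that acts alike on all cells of a pool would move both sexes the same way. In HSC-like cells with Xist, however, the median was -0.30, and with the sexes weighted equally it was 0.22. Members differed with Xist: Egr1 was at 770 and 807 CPM in control and chelator cells, but Fos at 756 and 608, Jun at 827 and 337 and Dusp1 at 245 and 139. Handling that differed between animals or sexes cannot be excluded by this. Whether the regimen, the particular animals in each pool or their handling lie behind the rest cannot be told apart. Animals were not told apart and there was 1 pool per condition. An effect of the regimen that depends on sex stays open as a hypothesis.

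The next is HSC-like cluster 11, led by Kcnb2, Matn4, Chrm3, Ncam2 and Vwf, of which 83.7% came from the control pool. Doublets would carry more RNA, but its median UMI count was only 1.20 times that of the other HSC-like clusters. It held no cell with Xist, where 30.9 of its sexed control cells would have had it at the rate of the other HSC-like clusters, in line with an origin in male animals. Whether the regimen, or single animals with a large clone of such cells, set its size cannot be told apart without a label per animal.

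The last is the lower level of Hspa1a and Hspa1b in the chelator pool of whole LSK. In HSC-like cells with Xist, Hspa1b was at 6.58 CPM (4.34 to 9.58) in control and 4.91 CPM (2.91 to 7.75) in chelator cells, and Hspa1a at 1.71 CPM (0.686 to 3.52) and 1.36 CPM (0.443 to 3.18), so the difference was not seen there for either gene beyond counting error. In whole LSK it did not rest on a few cells, since the 10 control cells with most Hspa1b UMIs held 13.3% of them. A general heat shock response in control cells remains undecided: the median of 7 other cytosolic chaperone genes was -0.048, with Hspb1 at -1.08, Hsph1 at -0.24 and Dnaja1 at -0.16, and the other 4 above -0.1. Stress during the sort, the regimen and the animals all stay open.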

How the results depend on the processing

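The 7 settings that concern sex, stress genes in the clustering, cluster 11 and haemoglobin-rich cells were chosen after the results were seen; no paired analysis was possible because the labels give no replicate numbers and each condition was 1 pool, which also rules out leaving a replicate out. Of 312 results recomputed to 3905 values, 3385 stayed within the width of the counting interval, 444 moved farther, and 76, with an interval that had left out 0 or, for a list, a median outside the central 95% of random lists, changed sign, 56 of these with cells of 1 sex alone. TMM and median-of-ratios scaling, called doublets kept, cell-cycle genes kept in the clustering, the other UMI minimums, gates split at the median, no thinning, Leiden resolution 0.5 and cells with both sex markers left out reversed none of the results they were run on, and moved none of those that answer a comparison; most of these settings concern only part of the 20 such results. Values reversed by that rule, and moved ones that answer a comparison, follow, while other moved values are not listed. The values listed are log2 ratios, list medians or points of share, and the cause was not tested except where cells left out or their sex show it. With cells with Xist alone, in whole LSK, gene ratios became Fos -0.21, Dynlt1b -0.058, Cdk5rap1 0.37, Fth1 -0.030, Ly6a 0.096, Zfp36 -0.40, Car2 0.13 and Gbp6 0.18, list medians Myc targets -0.025, stem cell identity 0.18, ageing 0.34, erythroid 0.043, S phase -0.029, G2 and M phase -0.13, immediate-early -0.19 and interferon gamma 0.0066, tags CD185 -0.10, CD150 0.15 and CD48 -0.53, and the percent of genes inside the fold window 98.0. In HSC-like cells they became Mki67 -0.061, Fosb -0.42, Fos -0.32, Dlk1 -1.48, Tacr1 0.63, Insm1 0.47, Vwf 0.23, Hlf 0.080, Sult1a1 -0.13, Alcam -0.17, Car2 0.066 and Hspa8 0.063, with list medians iron -0.074 and immediate-early -0.30, tags CD169 -0.12 and CD117 0.042 and 96.5% inside the fold window. In lymphoid-primed-like cells list medians became Myc targets 0.056 and ageing -0.068, and in megakaryocyte-primed-like cells Dlk1 -0.65 and the immediate-early median -0.33. Share differences became HSC-like 8.10, lymphoid-primed-like -4.20, erythroid-primed-like 0.971, HSC gate 9.45, MPP3 gate -0.260, S or G2M cells in whole LSK -4.18 and S or G2M cells among HSC-like cells -1.39. With cells with Y-linked transcripts alone, in whole LSK, gene ratios became Hbb-bs 0.82, Hbb-bt 0.33, Myl10 0.32, Kit -0.030, Heph -0.020, H2-K1 0.0057 and H2-D1 0.013, list medians cholesterol synthesis -0.030, Myc targets 0.014, stem cell identity -0.10, ageing -0.016, immediate-early 0.51, type I interferon -0.047, interferon gamma 0.0057 and MHC class II 0.031, and the tag CD11c 0.13. In HSC-like cells they became Myl10 0.57, Ly6a 0.10, Ifitm1 0.12 and Cxcl9 1.22, with list medians immediate-early 0.66 and interferon gamma 0.0021 and 98.5% inside the fold window, and in megakaryocyte-primed-like cells the median of stem cell identity -0.030. Share differences became HSC-like -2.05, lymphoid-primed-like 0.801, erythroid-primed-like -0.970, HSC gate 0.797 and S or G2M cells in whole LSK 5.64. With the sexes weighted equally, whole-LSK genes were Fth1 -0.0088, Ly6a 0.045 and Gbp6 0.12, list medians stem cell identity 0.036, ageing 0.14 and immediate-early 0.13, the HSC-like immediate-early 0.22 and the lymphoid-primed-like Myc targets 0.027. Without cluster 11, HSC-like genes were Ptprm 1.74, Insm1 0.54, Vwf 0.091 and Car2 0.00052, and the median of ageing 0.12. The intervals of Insm1, Vwf and Car2 then included 0. Without the 2 haemoglobin-rich control cells, and with no chelator cell left out, whole-LSK Hbb-bs was 0.86 and Hbb-bt 0.099. With Leiden resolution 1.5 and with the stricter cell filter, the lymphoid-primed-like median of Myc targets was 0.011 and 0.0066, and with that filter the HSC-like S phase median was -0.034. With the mean of per-cell CPM, whole-LSK medians were immediate-early 0.29 and type I interferon -0.010. HSC-like Hbb-bs was 0.13 with no cell filter and 0.088 with stress genes left out of the clustering. By centred log ratios, whole-LSK tags were CD185 -0.023, CD150 0.067 and CD48 -0.012, and HSC-like CD150 0.061. Depth limits the smaller classes most: within megakaryocyte-primed-like cells 1539 genes reached 1000 UMIs, against 9833 in whole LSK.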

Other observations

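The comparisons in this part were chosen after the results were seen, and they are given as values. Cdk5rap1, which encodes a tRNA-modifying enzyme, was at 26.5 CPM (24.7 to 28.4) in control cells with Y-linked transcripts and at 9.04 CPM (8.16 to 9.98) in chelator cells with them, while in cells with Xist it was at 18.8 CPM (17.2 to 20.6) and 24.3 CPM (22 to 26.9). In HSC-like cells the same 4 groups had 33.1, 10.0, 26.6 and 26.2 CPM. Myl10, a myosin light chain gene, was far higher in cells with Xist, at 166 CPM (161 to 171) in control and 115 CPM (110 to 121) in chelator cells, than in cells with Y-linked transcripts, at 21.0 CPM (19.4 to 22.7) and 26.3 CPM (24.8 to 27.8). Its lower pooled level in the chelator pool thus went with fewer cells with Xist there and with a lower level within them. Mid1 was higher in the chelator pool in both sexes, at 16.8 and 23.3 CPM in cells with Xist and at 10.7 and 29.6 CPM in cells with Y-linked transcripts.

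Within immediate-early genes the members did not move alike in the sexes. In whole LSK Egr1 was higher in the chelator pool in both, at 180 and 257 CPM with Xist and at 197 and 284 CPM with Y-linked transcripts. Within HSC-like cells it was at 770 (743 to 797) and 807 (778 to 836) CPM with Xist, and at 589 and 933 CPM with Y-linked transcripts. The whole-LSK values take in the make-up of the cells, whose part was not tested. Among cells with Xist the HSC-like share was 22.4% in control and 30.5% in chelator cells. Jun, the partner of Fos in AP-1, had 525 and 304 CPM with Xist and 339 and 462 CPM with Y-linked transcripts, so that its pooled ratio of -0.00046 hid opposite differences. Control cells with Xist thus had more Jun than any of the other 3 groups of cells, and chelator cells with Xist the least.

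Across genes, the chelator over control ratios of the sexes had a Spearman correlation of -0.16 over 4451 genes with at least 5000 UMIs in whole LSK, and of 0.0039 over 4965 genes with at least 1000 UMIs in HSC-like cells; sex-linked marker genes were left out. Pearson correlations were 0.22 and -0.061. Genes are not independent replicates. Counting error draws such correlations toward 0, and how far it did so here was not measured. In HSC-like cells the ratios with Xist came from only 318 control and 274 chelator cells. A value near 0 there thus does not show that the sexes differed. The ratios had the same sign in 43.6% and 50.5% of these genes.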
